A study of Mus musculus with 24 samples.

How the data were processed

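Brain tissue of conditional THAP1 knockout mice and of control mice carrying Nestin alone was profiled at postnatal day 21, in cerebellum, cortex and striatum. The labels give 24 arrays in 6 groups of 4, named here by group and by the number in the label. RNA was taken with TriZol from frozen tissue and turned into biotin-labelled cRNA with an Illumina TotalPrep kit, per the labels' protocols. The design text names 4 control and 4 knockout mice. No label ties an array to a mouse, so the labels do not say which arrays of different regions come from separate mice. Where arrays of a mouse resemble each other, p-values of the mean effect over regions are too small and those of differences between regions too large. Replicate numbers are not shared between groups, so no pairing by number exists.

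The deposited raw table holds, per the file headers, a linear bead intensity for each of 25697 probes on each array, with no normalization. The same deposited table holds a detection p-value for each probe and array. The raw values came from BeadStudio, per the submitters' processing notes, and its version is not given in the sources used here. The authors' processed values are a second deposited table of intensity on a linear scale. Its column medians were 11.6 on all 24 arrays, from 11.553 to 11.606, and its lowest values ran from -19.8 to -14.6. Each of its columns had a rank correlation of 1 with the raw column of the same array. Which background subtraction and which normalization the authors used stays unknown. Before log2 was taken, low values of the authors' table were set to a floor, which can shrink differences of dim probes. The table of probe genes gave 1 gene for 23978 probes, several for 0 and none for 1719. Of these, 23971 matched the annotation of assembly GRCm38.p6, through which 8 symbols were updated. The number of sample columns without a label was 0.

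Background was corrected on the raw intensities with limma, with the noise estimated from the detection p-values, an offset of 16 was added, and values were quantile normalized and taken to log2. Exactly 0 was given as the detection p for 49.2% of values. Probes with a detection p under 0.01 on at least 4 arrays were kept, which left 14994 and removed 10703. For 2755 genes several probes were kept, and the probe with the highest mean over the 24 arrays stood for the gene. This gave 11114 genes, of which 10238 had a name and 876 were unnamed probes. Group means of the 6 groups were fitted to all 24 arrays with lmFit and eBayes of limma, with an intensity trend (residual degrees of freedom 18, prior degrees of freedom 9.53). Contrasts were knockout minus control in each region, the 3 differences of these effects between regions, and their mean. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Differences are on the log2 scale with an offset, which understates changes of dim genes. Where a probe was detected on no array of a group, only a bound is given with the adjusted p of the fit. It is the brighter group's mean over the mean of the lowest detected signal of each dim array or the probe's own signal if higher.

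There were 30 gene lists, 14 of cell types and 16 of pathways, tested with camera at a preset correlation of 0.01, for lists with at least 5 measured genes, adjusted within a region. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance, and does not compare them with other genes. List means per array were compared by an exact permutation test over 70 orderings, two-sided, whose smallest p is 0.0286, adjusted over lists and regions. The design, the tests, the lists, the named genes' rule and all but 4 of the alternatives were chosen before the data were examined.

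Named genes followed a rule. For each region they were the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, Thap1, and for each list that passed or had at least 3 called members up to 4 members with the smallest p. Mbp, Mog and Mag were named in every region, and 1 item of the rule is not reported here. The 10 genes changed in the same direction in all regions with the largest mean, and up to 5 genes past the threshold for each difference between regions, were added. Unnamed probes and predicted genes count in the rule and may be given as a number.

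The fit was tested on simulated data of 12350 genes, of which 66 were changed by 0.5 on the log2 scale, 65 by 1 and 62 by 2, beside 1 changed list. A log2 change of 0.5 was recovered for 48.5% of changed genes in cerebellum, 43.9% in cortex and 48.5% in striatum, a change of 1 for 90.8, 92.3 and 95.4%, and a change of 2 for 100% in each. False calls numbered 11, 10 and 9. The changed list was recovered in each region with 0 other lists passing. Noise was drawn independently for each probe and array, and changed genes outside the list were drawn from those brighter than the median. The simulation therefore does not cover dim genes or genes that move together, and cannot show how often lists pass by chance on the real arrays.

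Alternatives were no background correction, median scaling, the authors' processed values, no filter on dim probes, probes detected on all 24 arrays, the mean of a gene's probes, each region normalized and fitted alone, array weights, no sex-specific genes, a minimum log2 difference of 0.5, camera with an estimated correlation, fry, and each array left out in turn. Another 4 were added after seeing the data. They were the Y-linked signal as a covariate, the order of label numbers as a random block, the median of the myelin list as a result, and the Oxt level as a covariate in striatum. The slide as a block was not run, because the files give no slides. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.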

Results

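Messenger RNA of the cerebellum, cortex and striatum was measured at postnatal day 21 on 24 Illumina bead arrays. The arrays fall into 6 groups of 4, a Nestin control and a Nestin THAP1 knockout group in each of 3 brain regions. THAP1 is a zinc finger transcription factor whose gene is mutated in an inherited dystonia, and Nestin names the neural progenitor gene whose promoter is used to delete genes in the nervous system. The mean signal ranged from 287 to 570 between arrays, and 47.2 to 54.5% of the 25697 probes were detected on each array. Knockout groups had on average 12743 detected probes in cerebellum, 13148 in cortex and 13215 in striatum, against 13002, 12544 and 12986 in the controls. The number of arrays limits the precision of every value.

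Tissue markers separated the regions as labelled on all 24 arrays, which does not exclude neighbouring tissue taken along. The markers fixed for each region averaged 9.11 to 9.65 on a log2 scale on the cerebellum arrays, against 5.13 to 5.84 elsewhere. Cortex markers averaged 8.47 to 8.84 on the cortex arrays and 6.32 to 7.53 elsewhere, and striatal markers 8.96 to 10.0 on the striatum arrays and 5.82 to 8.39 elsewhere. Across genes within arrays, which are not independent replicates, Pearson correlations were 0.976 to 0.990 between arrays of the same group, 0.977 to 0.989 between genotypes of a region and 0.899 to 0.968 between regions. Eif2s3y, a Y-linked gene, was high on 2 arrays and low on 2 arrays of every group, so both sexes were equally frequent in each.

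The targeted gene was examined first. Thap1 was read by 3 probes, which did not move alike. Probe ILMN_2603593 was detected on 8 of 12 control arrays and 0 of 12 knockout arrays (Fisher's exact test, two-sided, p = 0.00135), and ILMN_2907066 on 10 and 1 (p = 0.000644). Probe ILMN_1258989 was detected on 10 control and 12 knockout arrays (Fisher's exact test, p = 0.478). These tests treat arrays of different regions as independent, and p is too small where they share a mouse. Within a region the lowest p was 0.0286, for ILMN_2603593 in cortex and ILMN_2907066 in cerebellum (Fisher's exact test, 0.129 after adjustment over 3 probes and 3 regions). As ILMN_2603593 was detected on no knockout array, only a bound can be given, against the lowest signal of detected probes. Its signal was at least 1.51-fold higher in the control than in the knockout cortex (adjusted p = 0.0015 over 14994 probes), a call that ended with the authors' processed values (adjusted p = 0.167). Low values of that table were set to a floor, which can shrink the difference of so dim a probe. The lost call therefore does not show that the signal was unchanged. The bound was at least 1.19-fold in striatum (adjusted p = 0.0687) and at least 1.02-fold in cerebellum (adjusted p = 0.941), neither of which passed. ILMN_2907066 was likewise at least 1.08-fold higher in the control cerebellum (adjusted p = 0.823) and at least 1.18-fold in the control cortex (adjusted p = 0.277). In striatum, where 1 knockout array detected it, it differed by -0.43 (adjusted p = 0.514).

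ILMN_1258989, the brightest probe and therefore the one that stands for Thap1 among all genes, was higher in the knockout. It rose by 1.12 in cerebellum (SE 0.22, adjusted p = 0.014), with all 4 knockout arrays above all 4 control arrays. The difference was 0.82 in cortex (adjusted p = 0.0829) and 0.39 in striatum (adjusted p = 0.749). The cerebellar call ended without control replicate 18 (0.96, adjusted p = 0.100), knockout replicate 23 (0.98, adjusted p = 0.0938) or knockout replicate 24 (1.07, adjusted p = 0.0579), and with the region fitted alone (adjusted p = 0.0759). The place of the probes within Thap1 and the deleted part of the gene are not given in the sources used here, and a probe outside the deleted part checks nothing.

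**Figure D1:**
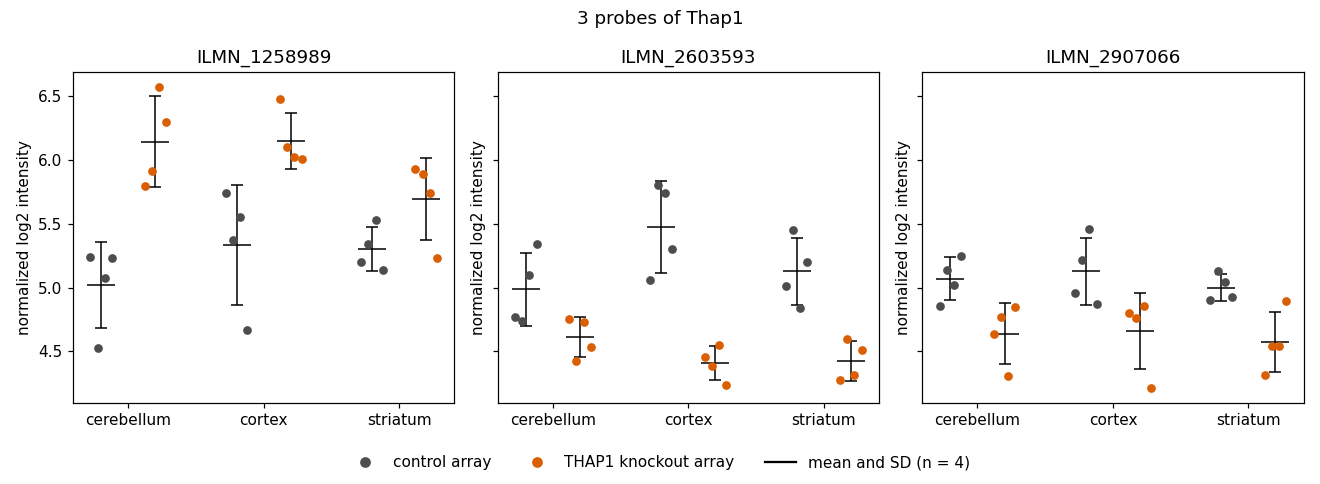
Normalized log2 intensity (vertical axis) of the 3 Thap1 probes on every array, by region, with control arrays in grey, knockout arrays in orange, and the mean and SD of each group of 4 in black. ILMN_1258989 lies higher in the knockout in cerebellum (difference 1.12), and ILMN_2603593, detected on no knockout array, was at least 1.51-fold higher in the control cortex.

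In the cerebellum 4 knockout arrays were compared with 4 control arrays. The largest changes were falls of Ech1, an isomerase of fatty acid oxidation, from 9.96 ± 0.11 to 7.49 ± 0.29 (SD, n = 4 each, log2 difference -2.47, SE 0.13), and of Cuedc2, which encodes a protein with a ubiquitin-binding CUE domain (-2.36, SE 0.14). Cln3, which encodes a lysosomal membrane protein mutated in juvenile Batten disease, also fell (-1.44), as did Mfsd13a (-1.49), Miga1, a mitochondrial fusion factor (-0.96), Prepl (-0.91) and Dpagt1, the enzyme that starts N-glycan assembly (-0.88). Among the genes that rose were Fam117a (1.46), Cyb5d2 (1.17), Lama2, a laminin chain (1.11), Snrnp35, a protein of the minor spliceosome (1.11), Atf5, a transcription factor of the integrated stress response (0.98), and Ppp2r3c, a phosphatase regulatory subunit (0.98). Lyrm1 (0.79), the inositol transporter Slc2a13 (0.73) and the ribosome assembly factor Imp4 (0.65) also rose. The 10 largest falls further held E430018J23Rik (-0.95) and 2 unnamed probes.

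In all, 26 of 11114 genes passed an adjusted p of 0.05 in the cerebellum, 12 higher and 14 lower, and 598 had an unadjusted p under 0.05. The 4 knockout values lay outside the 4 control values for all 26, and for 2.77% of all genes, where chance gives 2.86%. Among the genes named above, Ech1, Cuedc2, Cln3, Mfsd13a, Miga1, Dpagt1, Fam117a, Cyb5d2 and Ppp2r3c passed under every alternative that kept them and without every single array. Removing an array ended the call of Atf5 (control replicate 19 or 20, knockout replicate 21 or 22, adjusted p 0.0525 to 0.174), Imp4 (control 17 or 18, knockout 21 or 22, 0.0541 to 0.120), Lyrm1 (control 19 or 20, knockout 21 or 23, 0.0565 to 0.0870), Prepl (control 17 or 18, knockout 21, 22 or 23, 0.0546 to 0.154), Lama2 (knockout 21, 0.0633) or Slc2a13 (knockout 22, 0.0565). The call of Snrnp35 ended when its probes were averaged (0.72, adjusted p = 0.112). Median scaling ended the calls of Atf5, Imp4, Lama2, Lyrm1 and Slc2a13 (adjusted p 0.0693 to 0.739), the region fitted alone those of Atf5, Imp4, Lyrm1, Slc2a13 and E430018J23Rik (0.0678 to 0.155), the authors' values those of Atf5 and Prepl (0.0682 for both), and array weights that of Lyrm1 (0.0577).

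As a group, genes of the integrated stress and unfolded protein response were higher in the knockout cerebellum, with 17 of 19 measured members above 0 and a median log2 difference of 0.20 (camera, adjusted p = 1.86e-06). None of the 19 passed over all genes, although Slc7a5 did with the authors' values (adjusted p = 0.0273), and 4 rose when adjusted over the list alone. They were Slc7a5 (0.39) and Slc7a11 (0.52), amino acid transporters, Xbp1, a transcription factor of the unfolded protein response (0.46), and Sesn2 (0.44, detected on 1 of 4 control arrays). This list also passed with an estimated correlation (adjusted p = 0.0103). Averaged over its members, the list lay at 8.17 ± 0.14 on the knockout and 7.92 ± 0.11 on the control arrays (exact permutation p = 0.0571, where 0.0286 is the smallest possible).

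Another 3 lists were lower in the knockout cerebellum, none of which passed with an estimated correlation. Markers of Purkinje and other cerebellar neurons had a median of -0.19 over 13 genes (adjusted p = 0.0262, and adjusted p = 0.324 with an estimated correlation). Only Neurod1, a granule neuron transcription factor, fell when adjusted over the list alone (-0.66), while Eomes (-0.39), Barhl1 (-0.30) and Cbln3 (-0.28) did not. Over all genes Neurod1 passed under 4 alternatives, namely no background correction, median scaling, the authors' values and the mean of probes (adjusted p 0.00134 to 0.0385), and Barhl1 with the authors' values (0.0111). Pan-neuronal markers had a median of -0.11 over 16 genes (adjusted p = 0.0262, and 0.324 as the adjusted p with an estimated correlation). Celf4, an RNA-binding protein of neurons, fell when adjusted over the list alone (-0.47), and Rbfox3 (-0.34), Gap43 (-0.35) and Syn1 (-0.16, with 0.024 on its other probe) did not. Markers of mature oligodendrocytes and myelin had a median of -0.098 over 24 genes, 20 of them below 0 (adjusted p = 0.0262, and adjusted p = 0.835 with an estimated correlation). No member passed, including Mbp (-0.06), Mag (-0.11), Mog (-0.25), Opalin (-0.37), Mobp (-0.26), Gamt (-0.28) and Cldn11 (-0.22).

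Each of these 3 calls in the cerebellum depended on single arrays. The myelin call ended without control replicate 17 (adjusted p = 0.211) or 20 (0.224), or knockout replicate 22 (0.0824), 23 (0.102) or 24 (0.337). The Purkinje list lost its call without control replicate 17 (0.0906) or 18 (0.218), or knockout replicate 22 (0.195) or 23 (0.0720), and the pan-neuronal list without control replicate 19 (0.248) or 20 (0.0639), or knockout replicate 22 (0.195). The 4 passing lists of this region became 2 without control replicate 17 or 20 or knockout replicate 23, 1 without knockout replicate 22, and 7 without knockout replicate 21. Without the filter on dim probes only the stress response list passed, and the pan-neuronal call also ended when probes were averaged (adjusted p = 0.0739).

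In the cortex, the knockout group had lower levels of the same leading genes and of myelin genes. Cuedc2 fell from 10.4 ± 0.050 to 7.39 ± 0.098 (SD, n = 4 each, log2 difference -3.0, SE 0.14), and Ech1 (-2.64), Cln3 (-1.84), Dpagt1 (-1.24) and Prepl (-1.14) fell too. So did Opalin, a membrane protein of oligodendrocytes (-1.11), and Ppp1r14a, a phosphatase inhibitor and member of the myelin list (-1.03). Grb14, an adaptor of the insulin receptor, fell by 1.18 on its brightest probe and differed by -0.0019 on its other probe. The rising genes were led by Fam117a (1.57) and Erdr1 (1.18), followed by Snrnp35 (0.92), 6430411K18Rik (0.89), Chic1 (0.84), Slx4ip (0.83), Ppp2r3c (0.82), the stress granule protein Tia1 (0.81), the pseudouridine synthase Pus10 (0.79), Gpbp1l1 (0.78) and Lyrm1 (0.76). E430018J23Rik (-1.06) and 1 unnamed probe completed the 10 largest falls. Of the 4 control arrays, 1 detected Fam117a, Chic1 and Slx4ip and 2 detected Gpbp1l1, so that their differences are set against a group mostly not above background.

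Of 11114 genes, 61 passed in the cortex, 25 higher and 36 lower, with 1172 at an unadjusted p under 0.05. The groups did not overlap for 60 of the 61 and for 8.18% of all genes, against 2.86% by chance. The count fell to 16 without knockout replicate 16, 25 without knockout 15, 27 without knockout 14, 30 without control 9, 32 without control 12 and 38 without control 10, and it was 27 with median scaling (18 higher), 39 without the filter on dim probes, 107 with the region fitted alone and 220 with array weights. Cuedc2, Ech1, Cln3, Dpagt1, Prepl, Fam117a, Erdr1, Ppp2r3c and E430018J23Rik passed under every alternative that kept them and without every single array. The other calls ended when some arrays were left out.

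Without a single array the adjusted p rose to between 0.0557 and 0.0753 for Grb14 (control 9, knockout 15 or 16) and to 0.0553 for Snrnp35 (knockout 16). Chic1 lost its call without control 10, 11 or 12 or knockout 15 or 16 (0.0572 to 0.0944), Gpbp1l1 without control 10 or 12 or knockout 15 or 16 (0.0945 to 0.116) and Lyrm1 without control 12 or knockout 14, 15 or 16 (0.0582 to 0.0880). Pus10 lost it without control 12 or knockout 13, 14 or 15 (0.0591 to 0.0750), Tia1 without control 9 or 12 or knockout 13, 15 or 16 (0.0753 to 0.154) and Slx4ip without control 9 or 10 or any knockout array (0.0655 to 0.131). 6430411K18Rik passed only with all arrays or without control 10 (0.0640 to 0.199 otherwise), and Ppp1r14a only with all arrays or without control 11 (0.0623 to 0.148 otherwise). Averaging the probes of a gene ended the calls of Grb14, Pus10 and Slx4ip (adjusted p = 0.0640, 0.168 and 0.0932). The other probe of Pus10 differed by 0.15 (adjusted p = 0.860 over 14994 probes), that of Slx4ip by 0.27 (0.588) and that of Ppp1r14a by -0.81 (0.384). The calls of 6430411K18Rik, Chic1, Gpbp1l1, Ppp1r14a, Pus10, Slx4ip and Tia1 also ended without the filter on dim probes (adjusted p 0.0509 to 0.0908), and each of these ended under at least 1 other alternative as well.

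Markers of mature oligodendrocytes and myelin were lower as a group in the knockout cortex, with 22 of 24 genes below 0 and a median of -0.68 (camera, adjusted p = 8.75e-28, and adjusted p = 0.0548 with an estimated correlation). Of the 24, 10 fell over all genes tested and 21 when adjusted over the list alone. Transcripts of the myelin adhesion protein Mag (-0.77), Mal (-0.86), the tetraspanin Tspan2 (-0.69) and Mbp, the basic protein of compact myelin (-0.38), fell. Mog, a protein of the outer myelin surface, differed by -0.74 (adjusted p = 0.0535), and by -0.78 on its other probe (adjusted p = 0.0283 over 14994 probes). The mean of the list was 8.95 ± 0.21 on knockout and 9.55 ± 0.093 on control arrays, and every knockout array lay below every control array (exact permutation p = 0.0286, the smallest possible, 0.343 after adjustment over lists and regions). Such separation was not particular to myelin. In cortex the means of the stress response list (difference 0.16), the other lysosomal genes (-0.20) and the cholinergic and monoaminergic markers (-0.23) gave the same p.

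Several calls of single myelin genes in the cortex ended when an array was left out. Mag lost its call without control 9 or knockout 14 or 16 (adjusted p 0.0534 to 0.0753), Opalin without control 9 or knockout 15 or 16 (0.0557 to 0.0753), Tspan2 without control 9 or 11 or knockout 14 or 16 (0.0623 to 0.0753), Mal without control 9, 10 or 11 or knockout 14 or 16 (0.0559 to 0.123) and Mbp without control 9, 10 or 11 or knockout 14, 15 or 16 (0.0700 to 0.132). The other 2 probes of Mbp differed by -0.72 (ILMN_3081854, adjusted p = 0.140 over 14994 probes) and 0.018 (ILMN_3011353, adjusted p = 0.986), and averaging its probes ended the call (-0.36, adjusted p = 0.198). With median scaling the calls of Mag, Mal, Mbp, Opalin and Tspan2 ended (adjusted p 0.0524 to 0.401), and those of Mal and Mbp also with the authors' values (0.0628 and 0.230) and without the filter on dim probes (0.0510 and 0.127). Mog passed under 6 of the alternatives (adjusted p 0.0125 to 0.0434).

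A further 7 lists were lower and 1 was higher in the knockout cortex, and none of the 8 passed with an estimated correlation. Oxidative phosphorylation genes had a median of -0.29 over 17 members (adjusted p = 0.00027, and adjusted p = 0.170 with an estimated correlation). Of these, 3 fell when adjusted over the list alone, Cox5a (-0.31) and Cox4i1 (-0.31) of cytochrome oxidase and Atp5c1 of ATP synthase (-0.33), while Ndufb5 of complex I had -0.55. Over all genes Cox5a passed under 4 alternatives (adjusted p 0.010 to 0.0491). Microglia and macrophage markers had a median of -0.24 over 14 genes (adjusted p = 0.00328, and adjusted p = 0.245 with an estimated correlation), with no member passing, among them C1qc (-0.24), Ly86 (-0.46), Ctss (-0.50) and Aif1 (-0.39). Sphingolipid and myelin lipid synthesis genes had a median of -0.097 over 20 (adjusted p = 0.0105, and adjusted p = 0.287 with an estimated correlation). When adjusted over the list alone 5 of them fell, Fa2h (-0.73), Gal3st1 (-0.68), Ugt8a (-0.61), Cers2 (-0.50) and Elovl1 (-0.52, chosen after its value was seen). Over all genes Fa2h passed under 5 alternatives (adjusted p 0.0183 to 0.0447), and Gal3st1 and Cers2 with the region fitted alone (0.0118 and 0.0467) or array weights (0.0363 and 0.0384).

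Cholinergic and monoaminergic markers in the cortex had a median of -0.19 over 8 genes (adjusted p = 0.0105, and adjusted p = 0.0847 with an estimated correlation), lost without knockout replicate 14 (adjusted p = 0.0505) and without the filter on dim probes (-0.0995, adjusted p = 0.122). Ache, the enzyme that breaks down acetylcholine (-0.65), Tph2 of serotonin synthesis (-0.74) and Ddc (-0.47) fell when adjusted over the list alone, and Slc18a3 did not (-0.23). Over all genes Tph2 passed with the authors' values (adjusted p = 0.0322) and Ache with array weights (0.020). Markers of oligodendrocyte precursors and committed precursors had a median of -0.14 over 16 genes (adjusted p = 0.0382, and adjusted p = 0.410 with an estimated correlation). Of these, Enpp6 (-0.59), Olig1 (-0.45) and Bcas1 (-0.44) fell when adjusted over the list alone and Nkx2-2 did not (-0.30). Over all genes Enpp6 passed with the region fitted alone (adjusted p = 0.0226) or array weights (0.0213), and Olig1 with array weights (0.0457). That call ended without control replicate 9 (0.142) or 12 (0.0779) or knockout replicate 14 (0.112), 15 (0.0509) or 16 (0.20). It also ended without background correction (-0.083, adjusted p = 0.0593), without the filter on dim probes (-0.065, 0.0696) and with median scaling (-0.13 relative to all genes, 0.109). The other lysosomal genes passed (adjusted p = 0.0128, and adjusted p = 0.0771 with an estimated correlation) with a median of -0.046 and a mean of -0.20 over 16. Cln3 alone fell, with Npc2 (-0.52), Lamp1 (-0.28) and Ctsz (-0.37) not passing. The median was 0.10 with median scaling, which is -0.026 relative to all genes, and the call ended with probes detected on all 24 arrays (adjusted p = 0.207). The stress response list was higher with a median of 0.23 over 19 (adjusted p = 0.0353, and adjusted p = 0.245 with an estimated correlation), with no member passing, among them Slc7a5 (0.25), Mthfd2 (0.48), Herpud1 (0.23) and Psat1 (-0.29). It was lost with the authors' values (adjusted p = 0.143), with probes detected on all 24 arrays (0.128), and without control replicate 10 (0.116) or knockout replicate 13 (0.0553) or 14 (0.142).

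Choroid plexus and ependymal markers were all below 0 in the knockout cortex, with a median of -0.40 over 10 genes (adjusted p = 0.00152, and adjusted p = 0.311 with an estimated correlation). The call ended without knockout replicate 16 (-0.16, adjusted p = 0.192). Ttr, the transthyretin made by the choroid plexus, read 8.71 on that array, against 12.6 to 13.4 on the other knockout and 13.1 to 13.9 on the control arrays. No member passed, with -1.45 for Ttr, -0.61 for Sostdc1, -0.47 for Folr1 and -0.44 for Clic6.

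In the striatum the falls outnumbered the rises, and most of the leading falls beside the genes shared with the other regions were myelin genes. Ech1 fell from 9.77 ± 0.080 to 6.91 ± 0.16 (SD, n = 4 each, log2 difference -2.86, SE 0.13), and Cuedc2 (-2.05), the integrin subunit Itgad (-1.67) and Cln3 (-1.55) fell as well. The myelin genes Opalin (-1.13), Mobp (-1.09), Mal (-1.08) and Cnp (-1.08) fell to less than the control level on every knockout array. Prepl (-1.07), E430018J23Rik (-1.0) and Dpagt1 (-0.75) fell again. Fam117a (1.37), Plvap, a protein of fenestrated endothelium (1.11), Cyb5d2 (1.05), Ppp2r3c (1.03), Snrnp35 (0.99), Zfp597 (0.72), Lyrm1 (0.71), the estrogen receptor Esr1 (0.69), the relaxin receptor Rxfp3 (0.60) and Imp4 (0.57) rose. Esr1 was detected on 1 of 4 control arrays and Itgad on 2 of 4 knockout arrays. The 10 largest falls included 2 unnamed probes.

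Of 11114 genes, 60 passed in the striatum, 14 higher and 46 lower, with 822 at an unadjusted p under 0.05. The groups did not overlap for 48 of the 60 and for 3.79% of all genes, against 2.86% by chance. The count was 95 without knockout replicate 5, 36 without control replicate 1 and 30 without knockout replicate 8, and it was 26 with median scaling (7 higher), 28 with the region fitted alone and 5 with the Oxt level of each array as a covariate. The hypothalamic peptide genes Oxt (2.40, SE 0.49, adjusted p = 0.0115) and Avp (2.36, SE 0.55, adjusted p = 0.0409) were higher in the knockout striatum, with overlapping groups. Both were chosen after their values were seen. Oxt read 6.23 to 11.7 on the striatum arrays, against 4.63 to 5.00 in cerebellum. It was highest on knockout 5 (11.7) and knockout 8 (11.68), the arrays with the lowest mean of the striatal markers (9.05 and 8.96). Cln3, Cuedc2, E430018J23Rik, Ech1 and Ppp2r3c passed under every alternative that kept them and without every single array.

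Leaving out single arrays ended the calls of Dpagt1 (control 1 or 2, knockout 8, adjusted p 0.0586 to 0.0721), Opalin (control 1, knockout 8, 0.0535 to 0.0586), Lyrm1 (control 2 or 4, knockout 5, 7 or 8, 0.0508 to 0.0994) and Esr1 (control 1 or 2, knockout 6 or 8, 0.0968 to 0.181). Imp4 lost its call without control 1, 3 or 4 or knockout 5, 6 or 7 (0.0549 to 0.179), Plvap without control 1, 2 or 3 or knockout 5, 7 or 8 (0.0958 to 0.218), and Rxfp3 without any array other than control 2 (0.0548 to 0.206). Snrnp35, Fam117a, Prepl and Itgad lost theirs only with the Oxt covariate (adjusted p = 0.164, 0.154, 0.420 and 0.0509), as did Zfp597, Mobp, Mal, Cnp and Mog (0.0622, 0.0939, 0.173, 0.118 and 0.116). Median scaling ended the calls of Dpagt1, Lyrm1, Esr1, Imp4, Plvap and Rxfp3 (0.0762 to 0.435), and the region fitted alone those of Cyb5d2, Opalin, Dpagt1, Lyrm1, Esr1, Imp4 and Rxfp3 (0.0619 to 0.301). Plvap, Esr1 and Rxfp3 lost theirs under 5 or 6 alternatives each.

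Myelin markers as a group were lower in the knockout striatum, with 23 of 24 below 0 and a median of -0.69 (camera, adjusted p = 3.67e-39, and adjusted p = 0.0117 with an estimated correlation). Of the 24, 12 fell over all genes tested and 19 when adjusted over the list alone. Mog (-1.02) and Mag (-0.82) fell, the latter not with median scaling (adjusted p = 0.438) or the region fitted alone (0.0943), while the 3 probes of Mbp did not move alike. Its brightest probe differed by -0.09 (adjusted p = 0.900, and 0.08 with median scaling, which moved the median of all genes to 0.08), ILMN_3081854 fell by 1.25 (adjusted p = 0.0023 over 14994 probes) and ILMN_3011353 differed by -0.019 (adjusted p = 0.994). The list mean was 9.13 ± 0.35 on knockout and 9.82 ± 0.18 on control arrays, with every knockout array below every control array (exact permutation p = 0.0286, the smallest possible, 0.343 after adjustment over lists and regions). In striatum the means of the GABAergic interneuron markers (difference 0.16) and of the stress response list (0.071) gave the same p, with every knockout array above every control array. The stress response list did not pass camera in striatum. Oxt was higher on average in the same knockout group, with overlap between the groups. The median of the myelin list was -0.79 with the Oxt level as a covariate.

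Lipid synthesis genes were lower in the knockout striatum too. Sphingolipid and myelin lipid synthesis genes had a median of -0.16 over 20 (adjusted p = 8.24e-06, and adjusted p = 0.0797 with an estimated correlation). Of these 3 fell over all genes, Ugt8a, which makes galactosylceramide (-0.99), Fa2h, which hydroxylates fatty acids of myelin lipids (-0.98), and the elongase Elovl1 (-0.71), and 5 when adjusted over the list alone, with Cers2 (-0.59) and Gal3st1 (-0.68, chosen after its value was seen). Over all genes Cers2 passed when probes were averaged (adjusted p = 0.0433) or with the Y-linked covariate (0.0417). The call of Elovl1 ended without control 1, 2 or 4 or knockout 6, 7 or 8 (adjusted p 0.0602 to 0.280) and that of Ugt8a without knockout 8 (0.0757). Median scaling ended the calls of Elovl1, Fa2h and Ugt8a (0.566, 0.0980 and 0.0623), and the region fitted alone those of Elovl1 and Fa2h (0.352 and 0.0582). Cholesterol biosynthesis genes had a median of -0.19 over 17 (adjusted p = 7.85e-05, and adjusted p = 0.187 with an estimated correlation), with no member passing, among them Fdps (-0.33), Hmgcs1 (-0.26), Mvd (-0.42) and Nsdhl (-0.46).

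Markers of oligodendrocyte precursors and committed precursors in the striatum had a median of -0.24 over 16 genes (adjusted p = 0.000155, and adjusted p = 0.129 with an estimated correlation). Enpp6, a marker of newly forming oligodendrocytes, fell by 0.85, a call that ended without knockout replicate 7 (adjusted p = 0.0566) or 8 (0.0548), with median scaling (0.264) and with the region fitted alone (0.0699). Olig1 (-0.53) and Bcas1 (-0.44) fell when adjusted over the list alone, and Itpr2 did not (-0.35), while Olig1 passed over all genes with the Y-linked covariate (adjusted p = 0.0478). GABAergic interneuron markers were higher, with a median of 0.13 over 14 (adjusted p = 0.0393, and adjusted p = 0.0975 with an estimated correlation). Vip rose when adjusted over the list alone (0.49, detected on 1 of 4 control arrays), and Cck (0.56), Lhx6 (0.33) and Cort (0.32, with -0.21 on its other probe) did not. That call ended without control replicate 1 (0.0765), 2 (0.0632) or 3 (0.0603) or knockout replicate 5 (0.161) or 6 (0.0861). It also ended without background correction (0.069, adjusted p = 0.107), with the authors' values (0.085, 0.0887), with probes detected on all 24 arrays (0.067, 0.297) and with the Oxt covariate (0.16, 0.198). The 5 passing lists became 8 without knockout replicate 7.

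**Figure D2:**
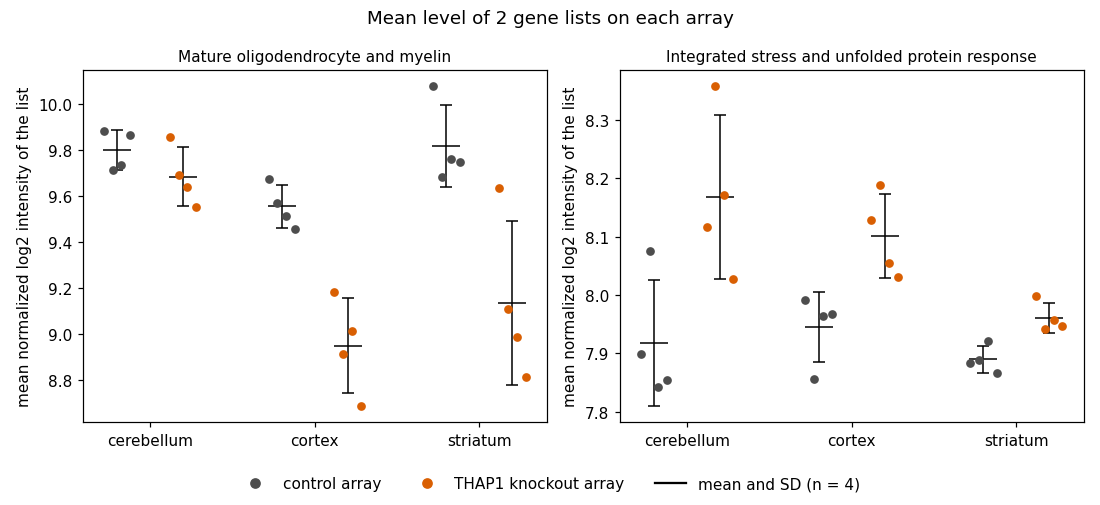
Mean normalized log2 intensity of the mature oligodendrocyte and myelin list and of the integrated stress and unfolded protein response list (vertical axes) on each array, by region, with control arrays in grey, knockout arrays in orange, and the mean and SD of each group of 4 in black. The myelin list averaged 8.95 in the knockout and 9.55 in the control cortex, and 9.13 and 9.82 in the striatum, without overlap of the groups. The groups did not overlap for the stress response list in cortex and striatum either.

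A change in the same direction in all 3 regions was called for 10 genes, 4 higher and 6 lower. Independent lists give 0.00022, which leaves out that regions may share mice, and other splits that keep the label order together in all regions gave at most 3. By the mean over regions they were Ech1 (-2.66, SE 0.077), Cuedc2 (-2.47), Cln3 (-1.61), Fam117a (1.47), Prepl (-1.04), Snrnp35 (1.01), E430018J23Rik (-1.0), Dpagt1 (-0.96), Ppp2r3c (0.94) and Lyrm1 (0.76), of which 9 were read by 1 kept probe only. The other kept probe of Snrnp35 differed by 0.34 in cerebellum, 0.69 in cortex and 0.52 in striatum. It passed in no region over all kept probes (lowest adjusted p = 0.217, in cortex). Ech1, Cln3, E430018J23Rik and Lyrm1 lie on chromosome 7, where genes with a mean effect were frequent, as given under other observations. Thap1 itself lies on chromosome 8, and the shares over chromosomes did not pass a permutation test (p = 0.097, adjusted 0.18). DNA of another mouse strain cannot be told apart from an effect of the knockout for any of the 10 genes, on chromosome 7 or elsewhere. Cerebellum and cortex shared 4 rising and 7 falling genes (0.027 and 0.045 for independent lists), cerebellum and striatum 7 and 8 (0.015 and 0.058), and cortex and striatum 4 and 18 (0.031 and 0.15). Of the 109 genes called in at least 1 region, none was called in opposite directions. Log2 differences of all genes correlated between regions across genes, which are not independent replicates, with r of 0.359, 0.319 and 0.354. These did not exceed what the arrays gave without a genotype effect, as r ran up to 0.369, 0.374 and 0.394 (medians 0.192, 0.226 and 0.205) over the 18 splits by label order with 2 arrays of each genotype on both sides. The number of genes shared by all regions was 8 to 11 without single arrays.

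**Figure D3:**
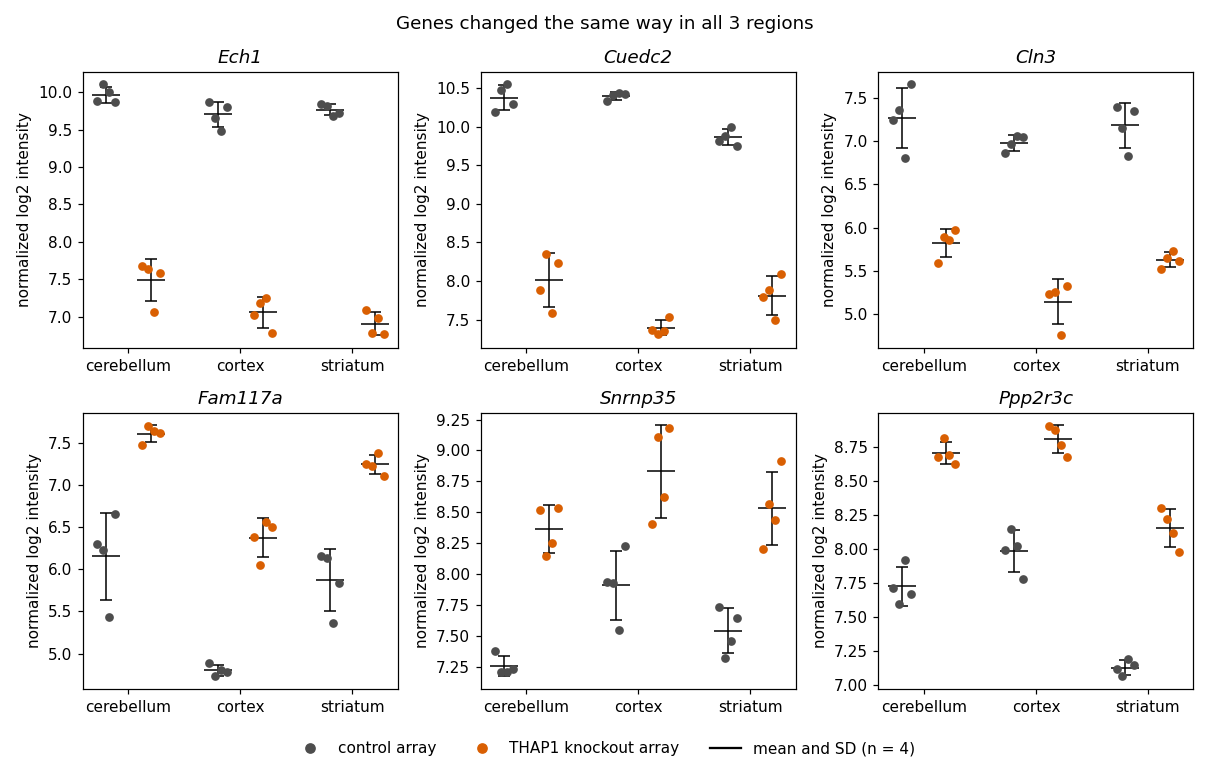
Normalized log2 intensity (vertical axis) of 6 genes called in the same direction in all 3 regions, by region, with control arrays in grey, knockout arrays in orange, and the mean and SD of each group of 4 in black. Ech1, Cuedc2 and Cln3 lie lower and Fam117a, Snrnp35 and Ppp2r3c higher in the knockout in every region.

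The mean effect over the regions was nonzero for 257 genes, 124 higher and 133 lower, with 1600 at an unadjusted p under 0.05. The design names 8 mice for 24 arrays and the labels do not tie arrays of different regions to mice, so these p-values treat arrays of a shared mouse as independent and are then too small if such arrays resemble each other. With the order of the label numbers as a random block 158 genes passed, and with median scaling 96 (34 higher).

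A difference of the knockout effect between regions was called for 2 genes. Fxyd6, a modulator of the sodium pump, fell in cerebellum by 0.64 and differed by 0.14 in cortex and 0.12 in striatum. Its difference of effects was -0.78 between cerebellum and cortex (SE 0.13, adjusted p = 0.0313) and -0.76 between cerebellum and striatum (adjusted p = 0.0485). Iqcj rose in cortex by 0.67 and had -0.55 in striatum (difference 1.22, SE 0.21, adjusted p = 0.0453), and its cortical call ended without any array other than control 12 (adjusted p 0.0553 to 0.137). It also ended under 5 alternatives (adjusted p 0.0534 to 0.310), with 0.19 without background correction and 0.33 with the authors' values, and the probe was detected on 1 of 4 control arrays. In striatum, Iqcj passed with the authors' values (-0.72, adjusted p = 0.0151). The count of genes per contrast was 1 each, with 434, 400 and 484 genes at an unadjusted p under 0.05 for cerebellum against cortex, cerebellum against striatum and cortex against striatum. Removing single arrays gave counts of 0 to 1, 0 to 9 and 0 to 2, and differed from the full data for 12, 21 and 19 of the 24 arrays. All 3 counts were 0 with median scaling and without the filter on dim probes.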

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

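All tests of explanations in this part were chosen after the result was seen, as were the splits by label order. The rule for reading the other counts over splits was also written after it, and the differences between regions were planned.

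Thap1 was not read alike by its 3 probes. ILMN_1258989 was 1.12 higher in the knockout cerebellum, while ILMN_2603593 was detected on 8 control and 0 knockout arrays. Detection of ILMN_2603593 and ILMN_2907066 on fewer knockout arrays (Fisher's exact test over 24 arrays, higher p 0.00135, and 0.129 as the lowest adjusted p within a region) goes against an exchange of control and knockout labels. Such an exchange stays open because the third probe, ILMN_1258989, rose. The rising probe may lie outside the deleted part, and its difference of 1.12 cannot be told apart from other sources because the place of the probe in the gene is not given in the sources used here. No biological explanation was tested.

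The myelin list was lower in cortex and striatum, with medians of -0.68 and -0.69. Processing of the signals as the whole cause is argued against by no background correction, median scaling and the authors' values. The highest median relative to all genes under these was -0.543, in cortex without background correction. For the same loss at every stage of the oligodendrocyte lineage, the precursor list had medians of -0.14 (SD of members 0.26) and -0.24 (SD 0.27). These lay above those of myelin by more than this SD. The SD is a spread over genes and not the error of a median, so the smaller fall of this list cannot decide on an equal loss. Tissue rich in Oxt as the whole cause in striatum is argued against by a median of -0.785 with Oxt as a covariate, although of 60 gene calls 55 ended, 54 with a larger SE (median ratio over the 60 of 1.45) and 27 with a difference as large, while Avp (2.36 to 0.26), Plvap (1.11 to 0.57) and Prepl (-1.07 to -0.64) shrank most apart from Oxt itself. Fewer cells of the whole lineage, to a lesser degree in precursors, stay open. The list of precursors and committed precursors was lower in both regions (camera, adjusted p = 0.410 and 0.129 with an estimated correlation). Among its members were Enpp6, a marker of newly forming oligodendrocytes (-0.59 and -0.85), Olig1 (-0.45 and -0.53) and Bcas1 (-0.44 in each). Pdgfra and Cspg4, markers of the earliest precursors, averaged 0.056 (SE 0.14) and -0.031 (SE 0.033), which is no fall beyond the SE. Other differences in the tissue taken, and loss of Thap1 acting on mature oligodendrocytes, stay open and untested.

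Counts of genes were set against other splits of the same arrays. In 1 of 35 splits, the real one, the count was as large for cerebellum (26, highest other 5), for cortex (61, highest other 3) and for striatum (60, highest other 20). This argues against chance for these counts, although 1 of 35 is the smallest share that such splits can give. The same holds for genes changed in the same direction in all regions (10, highest other 0, 1 of 100 splits, and highest other 3, 1 of 35 that keep the label order together), for the mean effect (257, highest other 17, 1 of 100) and for the mean effect over such splits by label order (257, highest other 70, 1 of 35). Chance was not excluded for the counts of lists, with 11 of 35 splits as large in cerebellum (4, highest other 7), 2 of 35 in cortex (9, highest other 9) and 14 of 35 in striatum (5, highest other 7). The split of the cortex that gave as many lists follows the Y-linked signal. For differences between regions, with 1 gene each, 4 of 100 splits gave as many for cerebellum against cortex, 12 for cerebellum against striatum and 8 for cortex against striatum (highest other 3 in each). Of the 35 splits by label order 3, 3 and 4 did (highest other 2, 2 and 5), so that chance is not excluded for any of them.

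The effect of the knockout on Fxyd6 differed by -0.78 between cerebellum and cortex and by -0.76 between cerebellum and striatum, and that on Iqcj by 1.22 between cortex and striatum.

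Differences of list effects between regions passed camera for 21 combinations. Between cerebellum and cortex the median difference was 0.54 for myelin, 0.16 for oligodendrocyte precursors, 0.31 for microglia, -0.15 for pan-neuronal, -0.19 for Purkinje, 0.48 for choroid plexus and 0.14 for oxidative phosphorylation genes. Between cerebellum and striatum it was 0.64 for myelin, 0.24 for oligodendrocyte precursors, 0.14 for microglia, 0.16 for endothelial, -0.14 for pan-neuronal, -0.18 for GABAergic, 0.075 for cholesterol, 0.16 for sphingolipid, 0.20 for stress response and 0.24 for cell cycle genes. Between cortex and striatum it was -0.066 for GABAergic, -0.39 for cholinergic, -0.46 for choroid plexus and -0.28 for oxidative phosphorylation genes. With an estimated correlation the GABAergic (adjusted p = 0.0419) and cholinergic (adjusted p = 0.0383) differences between cortex and striatum passed, and 0 of the others did.

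Of 330 groups of 4 arrays tested for an array far from the others, 17 had one (5.15%, where chance gives about 5%). In cerebellum they were Ech1 on knockout replicate 23 (7.07, others 7.58 to 7.68), Imp4 on knockout 21 (9.44, others 9.22 to 9.25) and Snrnp35 on control 17 (7.37, others 7.21 to 7.23). On cortex knockout replicate 15 they were Cln3 (4.76, others 5.23 to 5.33) and Cox4i1 (13.07, others 13.27 to 13.30), and on knockout 16 Herpud1 (10.90, others 11.04 to 11.06), Ndufb5 (7.75, others 8.13 to 8.20), Ugt8a (9.46, others 10.27 to 10.40) and the Thap1 probe ILMN_2907066 (4.22). On cortex control arrays they were Mthfd2 on replicate 10 (4.54, others 5.19 to 5.29), Nkx2-2 on 12 (7.62, others 7.37 to 7.41), Ugt8a on 12 (10.40, others 10.79 to 10.83) and Opalin on 9 (10.04, others 9.44 to 9.52). In striatum they were Cck on control 3 (6.18, others 6.84 to 6.94), Prepl on control 3 (11.59, others 10.85 to 10.91), Opalin on control 1 (10.29, others 9.58 to 9.69) and Cyb5d2 on knockout 8 (5.98, others 6.56 to 6.67).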

How the results depend on the processing

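The Y-linked covariate, the Oxt covariate, the label order block and the myelin median as a result were chosen after seeing the data, and the other alternatives were planned. Values were counted over the named genes, the Thap1 probes other than ILMN_1258989 and the passing lists other than myelin, under all alternatives. Of these, 2538 kept direction and side of the threshold, 326 no longer passed, 44 newly passed and 4 lost the sign of their difference. The 4 were 2 at a value of 0 and 2 under median scaling, which moves all genes. ILMN_1258989 and the myelin list are not in these counts and are given apart. Where no reason is given below, the cause was not tested. Signal over background limits dim probes, whose differences shrink with the offset.

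Median scaling gave 27 genes in cortex (18 higher, 9 lower), 26 in striatum (7 and 19), 96 for the mean effect (34 and 62), 0 for each of the 3 differences between regions and 8 lists in striatum. It moved the median of all genes by -0.104 in cerebellum, 0.127 in cortex and 0.083 in striatum, and relative to these the myelin list had -0.11, -0.66 and -0.69. It gave the other lysosomal list in cortex 0.10 (adjusted p = 0.0495) and Mbp in striatum 0.076, which relative to all genes are -0.026 and -0.0072 and so come from the scaling. The authors' values gave 51 genes in cerebellum (23 and 28), 6 for cerebellum against cortex, 3 for cerebellum against striatum, a myelin median of -0.082 in cerebellum (adjusted p = 0.0913), and 0 for Iqcj in cerebellum and for Thap1 probe ILMN_2907066 in striatum, where values lay at the floor. Without the filter, which tests more genes, 39 genes passed in cortex (13 and 26), 0 for each difference between regions and 1 list in cerebellum, with a myelin median of -0.092 there (adjusted p = 0.0791). No background correction gave 0 for cerebellum and for cortex against striatum, and array weights and probes detected on all 24 arrays gave 0 for cortex against striatum. Array weights gave 220 genes in cortex (118 and 102).

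Each region normalized and fitted alone gave 13 genes in cerebellum (5 and 8), 107 in cortex (39 and 68) and 28 in striatum (6 and 22). It gave Thap1 at 1.12 in cerebellum (adjusted p = 0.0759). The normalization and the number of arrays changed together here, so their parts cannot be told apart. With an estimated correlation 1, 0 and 1 lists passed in cerebellum, cortex and striatum, and the myelin medians of -0.098 in cerebellum (adjusted p = 0.835) and -0.68 in cortex (adjusted p = 0.0548) no longer did. Fry passed 1 list in cerebellum, without the myelin list (-0.098, adjusted p = 0.804), and 3 in cortex. Over the alternatives other than left-out arrays the adjusted p of the myelin list ran from 0.0046 to 0.835 in cerebellum, 2.61e-29 to 0.0548 in cortex and 3.41e-41 to 0.0117 in striatum. The Y-linked covariate gave 0 for cerebellum and for cortex against striatum, the Oxt covariate 5 genes in striatum (1 and 4), and the label order block 158 for the mean effect (60 and 98, correlation 0.0845). Leaving out sex-specific genes changed no count.

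Leaving out each array gave 19 to 30 genes in cerebellum, 16 to 44 in cortex and 30 to 95 in striatum, 8 to 11 in the same direction in all regions and 180 to 295 for the mean effect. Differences between regions ran from 0 to 1 for cerebellum against cortex, 0 to 9 for cerebellum against striatum (9 without striatum knockout replicate 5) and 0 to 2 for cortex against striatum. Lists ran from 1 to 7 in cerebellum, 6 to 10 in cortex and 4 to 8 in striatum, and myelin medians from -0.16 to -0.054, -0.72 to -0.57 and -0.92 to -0.57. Thap1 ran from 0.96 to 1.24 in cerebellum, 0.60 to 0.95 in cortex and 0.31 to 0.55 in striatum. Among named genes, the calls ended by median scaling numbered 26, by each region alone 22, by no filter 14, by the authors' values 11, by the mean of probes 6, by array weights 5, by no background correction 4, by the Y-linked covariate 1 and, in striatum, by the Oxt covariate 24. No paired analysis of knockout with control was possible because the groups share no replicate numbers, and the label order block joins regions of a genotype only.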

Other observations

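All tests of explanations in this part were chosen after the result was seen, and the mean effect and the list tests were planned. Gusb, the lysosomal enzyme beta-glucuronidase, was lower in the knockout by similar amounts everywhere, with -0.82 in cerebellum, -0.67 in cortex and -0.73 in striatum (adjusted p = 0.118, 0.131 and 0.118). It passed in no region over all genes, fell in each when adjusted over its list alone, and had a mean effect of -0.74 (SE 0.12, adjusted p = 0.000277). Its other kept probes had mean effects of -0.57 (ILMN_2741114) and -0.18 (ILMN_2768026). By the mean effect Gdpd3 fell by 1.41, Itgad by 1.18, Mfsd13a by 1.03, the lysosomal cholesterol carrier Npc2 by 0.42 and the dopamine receptor Drd2 by 0.47. Cyb5d2 (1.00), the neurotrophin Bdnf (0.51) and the glutamate transporter Slc17a6 (0.35) rose. Other kept probes gave -0.89 for Itgad, 0.89 for Cyb5d2 and 0.13 for Bdnf. All of these genes were chosen after their values were seen, and the Oxt level of the striatum was not held fixed for their mean effects. Over the regions 5 lists passed. Myelin genes had a mean-effect median of -0.51, with 24 of 24 below 0 and 18 fallen (adjusted p = 0.0228 with an estimated correlation). The stress response list had 0.17, with 3 risen, Xbp1 (0.26), Herpud1 (0.20) and Slc7a11 (0.36), and sphingolipid genes -0.083, with 5 fallen, Fa2h (-0.60), Ugt8a (-0.53), Gal3st1 (-0.49), Elovl1 (-0.42) and Cers2 (-0.40). Oligodendrocyte precursor genes had -0.049, with Olig1 (-0.40) and Enpp6 (-0.45) fallen, and cholesterol genes -0.15. The last 4 did not pass with an estimated correlation (adjusted p = 0.0652, 0.115, 0.447 and 0.447).

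Another 17 lists passed in no region. Their medians in cerebellum, cortex and striatum were 0.037, -0.027 and 0.087 for 18 astrocyte genes, 0.036, -0.023 and -0.086 for 15 endothelial genes, -0.043, 0.11 and 0.10 for 12 excitatory neuron genes, and -0.0064, -0.11 and -0.14 for 14 striatal projection neuron genes. They were 0.027, -0.12 and -0.12 for 11 meningeal genes, -0.62, -0.55 and 0.12 for 5 red blood cell genes (lowest adjusted p = 0.0622), -0.044, -0.028 and -0.048 for 12 glycosaminoglycan degradation genes, and 0.075, 0.018 and -0.018 for 16 genes of the p53 response. Cell cycle genes (13) had 0.090, 0.0085 and -0.11, THAP family and partner genes (11) 0.00051, -0.080 and -0.027, synaptic genes (12) -0.012, 0.12 and -0.0030, and immediate early genes (14) 0.037, -0.060 and -0.089. Innate immune genes (14) had 0.0091, 0.057 and -0.0099, reactive glia genes (14) 0.0041, -0.049 and 0.00032, ribosomal protein genes (11) 0.013, -0.075 and -0.068, growth hormone axis genes (15) 0.00075, 0.031 and -0.010, and thyroid hormone responsive genes (11) -0.062, -0.15 and -0.22.

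Genes with a mean effect were most frequent on chromosomes 7 (31 of 793, 3.91%) and 8 (23 of 560, 4.11%), where Thap1 lies on chromosome 8, against 0.70 to 2.97% on the other autosomes and X. Changes limited to single probes stay open on these 2 chromosomes, as 8 of 12 other probes of 10 genes had the sign of the first (66.7%, exact 95% interval 34.9 to 90.1, against 73 of 89 over all chromosomes) and 44 named genes had no other kept probe. The probes without that sign included ILMN_2603593 and ILMN_2907066 of Thap1, the targeted gene. DNA of another mouse strain, which can be linked to Thap1 only on chromosome 8, may add to these frequencies. It cannot be told apart, because 4 statistics were tried and none passed after adjustment. The fullest window of 50 tested genes held 8 (random mean 5.72, permutation p = 0.018, adjusted 0.072) and for genes called in any region 4 (3.74, p = 0.62), pairs within 10 genes numbered 64 (55.5, p = 0.14, adjusted 0.18), and shares over chromosomes gave 28.5 (19.4, p = 0.097, adjusted 0.18). The bound set for the pairs was poor, since a p that misses the threshold excludes nothing and 64 lies above the random mean.

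Arrays of different regions at the same place in the order of label numbers may share a mouse. Their deviations from the group means correlated by 0.178 on average (24 pairs, 23 above 0), with a permutation p of 6e-05 over 100000 permutations. In every region Eif2s3y was low, high, low and high on the control arrays in this order. On the knockout arrays it was low, low, high and high. Arrays at the same place therefore had the same sex, which goes with a shared mouse. The permutation did not hold sex fixed, so part of the correlation may come from sex. Both are hints from the data and not from the design. If arrays share mice, p-values of the mean effect are too small and those of differences between regions too large.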
